A study of Mus musculus with 18 samples.

How the data were processed

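RNA was extracted from whole pancreas and liver with TRI reagent and made into libraries by a bulk form of MARS-seq, per the labels' protocols. MARS-seq reads the 3′ ends of transcripts, so a count does not depend on transcript length and says nothing of the rest of the gene. Per the submitters' processing notes, cutadapt and STAR were used with the mouse build mm10. Versions, the counting tool, the annotation, the use of strand and the collapsing of molecular barcodes were not given in the sources used here. The deposited tables hold whole-number counts per gene, 1 table for each tissue, per the file names and the values. The authors call these counts corrected and do not say for what, so the p-values hold only if the correction left them close to counts. No normalisation was visible, since totals differed between libraries.

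Each table listed 55291 gene symbols, of which 53292 matched a symbol of GENCODE mouse release 21 (mm10), used for positions, gene types and gene spans. 35017 genes had 0 counts in every pancreas library and 36739 in every liver library. All 18 libraries were assigned to tissue, genotype, replicate and (pancreas only) sex from the labels, and 0 columns were left over. No 2 libraries were identical. The labels do not say whether a sample is a separate animal, and if some are not, p-values measure the spread between samples only.

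CPM is counts scaled to a library total of 1000000. Tests used edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM scaling, estimateDisp, a robust quasi-likelihood fit and its F test, with Benjamini-Hochberg adjustment over the genes tested in a comparison and a threshold of 0.05. The 11 pancreas libraries were fitted together with genotype and sex, so that all groups share an estimate of the spread, and all HOM were male. The 7 livers were fitted with genotype alone. The sex difference came from the same pancreas fit, and the interaction of genotype and sex from the 8 WT and HET pancreata. Filtering left 3719 genes in pancreas, 2400 for the interaction and 4803 in liver. Otub2 did not pass the filter and was tested in fits with no filter beyond 1 count. The common dispersion was 2.75 in pancreas (a biological coefficient of variation of 166%, 7 residual degrees of freedom) and 0.125 in liver (35.4%, 5 residual degrees of freedom).

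Before the data were examined, 45 gene lists covering cell types, pathways, RNA quality and sex were fixed, with the tests, the alternatives and the rule for naming genes. The rule took Otub1 and Otub2, the 10 genes with the largest and the 10 with the smallest log2 fold change among those past the threshold, or, with fewer than 5 past it, the 5 with the smallest p in each direction, and up to 4 members with the smallest p of each list described. Predicted genes (Gm and Rik symbols) and antigen receptor segments were left out of it. Another 4 lists (2 of stomach, 1 of intestine and 1 of skin and forestomach genes) were drawn up after the leading genes of 2 pancreas libraries were seen. Lists with at least 5 tested members, 9 in pancreas and 28 in liver, were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01 and the design of the comparison, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. No call of a list held with an estimated correlation or with fry. Members were also adjusted over the list alone. Where a group had 0 counts of a gene, levels are given in place of fold changes, with the limit of 3 counts over the summed counts of the group. Intervals of single shares are Wilson intervals at 95% confidence. Limits and intervals cover counting error only.

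Alternatives were DESeq2 1.42.0 (Wald test, same design), DESeq2 size factors in edgeR, scaling without the acinar enzymes, no filter, a mean of at least 10 CPM, no sex covariate, males only, only the 2 groups compared, no robust fit, the replicate number as a block, and leaving out each library in turn. Chosen after the data were seen were scaling by total counts, leaving out HET 11 and HET 16 together, exact permutation tests of Otub2 and its test with HET and HOM pooled. Scaling by DESeq2 size factors moved the median log2 fold change of all genes by −0.16 in HOM against WT and −0.12 in HOM against HET. Scaling by total counts moved it by −0.24 in HOM against WT, −0.57 in HET against WT, 0.37 in HOM against HET and −0.10 in liver. Every list called kept its direction under these scalings. Camera sets a list against the other genes, so a shift common to all genes could hardly have changed it. The TMM factors were 0.175 in HET 11, 0.268 in HET 16 and 1.29 to 1.61 in the other pancreata.

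The fits were tested on simulated data: negative binomial counts with the means, library sizes and dispersion of the real libraries, with 200 changed genes in each of 3 draws, 120 genes for each fold size over the draws. In liver 8.33% of 2-fold, 55% of 4-fold, 90.8% of 16-fold and 96.7% of 64-fold changes were called among 4803 genes. In pancreas 0% were called up to 64-fold among 3719 genes, and of 1024-fold changes 0% in HOM against WT, 0% in HET against WT and 5% in HOM against HET. The pancreas gene test could thus not have found most changes of single genes. Lists of 20 genes shifted 4-fold had an unadjusted camera p under 0.05 in 3 of 3 draws in each comparison and unshifted lists in 0 of 3. Genes were drawn independently of each other there. The real oxidative phosphorylation list had an estimated correlation of 0.655 in pancreas HOM against HET. The draws therefore do not show how often unchanged lists of correlated genes are called.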

Results

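Gene expression was measured by RNA sequencing in pancreas and liver of mice carrying 2, 1 or 0 intact copies of Otub2, which encodes a deubiquitinase of the OTU family. The study concerns the part this enzyme plays in the pancreatic beta cell. Animals with 2 copies are called WT, animals with 1 copy HET and animals with 0 copies HOM. Pancreas gave 11 libraries: 3 WT, 5 HET and 3 HOM. Sex was given for the pancreas donors (WT 1 female and 2 males, HET 2 females and 3 males, HOM 3 males). Liver gave 7 libraries, 2 WT and 5 HET, with no sex stated. Libraries are named by genotype and the submitters' replicate number. Total counts per pancreas library ran from 49502 (HET 9) to 1326541 (HET 11), with a mean of 111060 ± 67644 in WT (SD, n = 3), 457466 ± 547269 in HET (SD, n = 5) and 128171 ± 77222 in HOM (SD, n = 3). Liver libraries held 155201 (WT 1) to 1686234 (HET 5) counts. Rank correlations of expression between 2 livers were 0.751 to 0.877 across 6369 genes, and between 2 pancreata −0.354 to 0.677 across 6131 genes, which are not independent replicates.

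Otub2 had counts in all 3 WT pancreata and in few of the others. The gene (ENSMUSG00000021203.15, protein-coding) lies on chromosome 12, positions 103388682 to 103406350 on the plus strand of mm10. WT 11, WT 12 and WT 16 held 3, 4 and 3 counts, a mean of 38.6 ± 23.6 CPM (counts scaled to a library total of 1000000; SD, n = 3). HET pancreata held 1 count in HET 16 and 0 in the other 4 (0.298 ± 0.667 CPM, SD, n = 5), and HOM pancreata 1 count in HOM 10 and 0 in the other 2 (1.63 ± 2.81 CPM, SD, n = 3). With edgeR the log2 fold change was −3.56 ± 2.78 (SE) in HET (adjusted p = 0.684) and −3.65 ± 3.48 in HOM (adjusted p = 1). Neither passed the threshold. DESeq2 did not call it either (adjusted p = 1.00 in HOM, no adjusted p given in HET). Two-sided exact permutation tests of the CPM values, chosen after the counts had been seen, gave p = 0.0357 for HET (0.0714 adjusted over 4 tests) and p = 0.1 for HOM (0.133 adjusted), the smallest p that 20 splits allow. The difference of HET and HOM pooled from WT was −37.8 CPM (exact permutation p = 0.0121, 0.0485 adjusted, 8 libraries against 3). This too is the smallest p that its 165 splits allow, so the 3 p values differ by the number of splits alone. In liver Otub2 was near the limit of detection in both genotypes, at 3.22 ± 4.56 CPM in WT (SD, n = 2, 1 count) and 1.80 ± 1.39 in HET (SD, n = 5, 5 counts), with a log2 fold change of −0.34 ± 1.88 (edgeR, adjusted p = 0.933). The 1 WT count was in WT 1, so the direction rests on that library. The libraries read transcripts from the 3′ end, and the deleted part of Otub2 was not given in the sources used here, so these counts may check nothing about the labels. The WT pancreata were also among the libraries with many receptor gene counts described below, in which a count need not come from a spliced transcript. The paralog Otub1 (chromosome 19, 7198202 to 7206316, minus strand) had 9.36 ± 8.28 CPM in WT pancreas, 59.5 ± 83.5 in HET and 0 in HOM, with all HET counts in HET 11 (163) and HET 16 (117), and 58.1 ± 45.8 in WT and 68.0 ± 28.0 in HET liver.

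**Figure D1:**
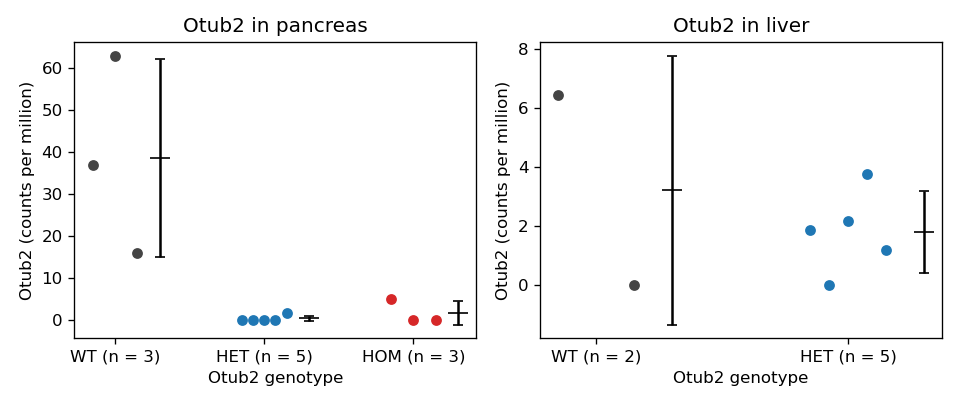
Otub2 in CPM (vertical axis) by genotype (horizontal axis) in pancreas and liver; points are libraries and bars the mean ± SD. All 3 WT pancreata held Otub2 counts (38.6 ± 23.6 CPM), against 1 count in 1 of 5 HET and 1 count in 1 of 3 HOM pancreata.

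The pancreas libraries were of 2 kinds. HET 11 and HET 16 were led by the stomach and pancreas genes Clps (colipase, a cofactor of pancreatic lipase), Pgc (the pepsinogen progastricsin) and Tff1 (a trefoil peptide of gastric mucus). Clps had 188192 counts in HET 11 and 25493 in HET 16, Pgc 165171 and 80604, and Tff1 104358 and 37562. A list of 15 stomach mucosa genes, drawn up after these leading genes were seen, held 25.4% of the counts of HET 11 (Wilson interval at 95% confidence, 25.4 to 25.5) and 22.3% of HET 16 (22.2 to 22.4), against 0.00184% to 3.11% in the other 9. Protein-coding genes took 94.96% and 91.6% of counts in HET 11 and HET 16 and 60.0% to 68.8% in the other 9. Cytosolic ribosomal protein genes took 5.30% and 5.81% in HET 11 and HET 16. By group this was 0.399% ± 0.225 in WT (SD, n = 3), 2.63% ± 2.68 in HET (SD, n = 5) and 0.563% ± 0.0535 in HOM (SD, n = 3). Acinar digestive enzymes, the main product of the exocrine pancreas, were scarce in most libraries: 495 ± 574 CPM in WT (SD, n = 3), 48970 ± 69817 in HET (SD, n = 5) and 8143 ± 6794 in HOM (SD, n = 3). Clps, a member of this list, held 37752.5 CPM of the HET and 5285 of the HOM mean, and the phospholipase gene Pla2g1b 11080 and 2570. Pnliprp1 made up most of the WT mean, at 387 CPM, against 52.8 in HET and 289 in HOM. Prss2, a trypsinogen, and Cel, a lipase, had 0 counts in all 11. Among genes that most cells use, Eef1a1, a translation factor, had 4 counts in WT 11 and 0 in the other 10 pancreata, HET 11 with its 1326541 counts among them, and Gapdh had 0 to 8, where the livers held 13 to 83 counts of Eef1a1 and 3 to 74 of Gapdh. Scaled to library size, both genes were low beside Actb in liver too. Liver Eef1a1 had 97.8 CPM in HET and 103 in WT, Gapdh 31.9 and 57.9, and Actb 3629 and 3614. Actb and Rplp1 were not low throughout, with 12 to 18295 and 0 to 9498 counts in the pancreata. Islet hormone genes held 141 ± 245 CPM in WT, 728 ± 825 in HET and 236 ± 94.5 in HOM (SD). Ins1 had 79 counts in WT 16, 59 in HET 10, 30 in HET 16, 51 in HOM 10 and 16 in HOM 21, and 0 in the other 6, Gcg had 0 everywhere, and Ghrl, a hormone of stomach and islets, had 2643 in HET 11. Ins2, the other insulin gene, had 0 counts in WT and HET and 3 in HOM. Ghrl held 555 CPM of the HET mean, 1.77 of the WT mean and 77.6 of the HOM mean. Ins1 held 160, 140 and 124 CPM in HET, WT and HOM. The beta-cell identity genes summed to 1270 ± 856 CPM in WT, 866 ± 713 in HET and 1261 ± 472 in HOM (SD). Fewer than 5 members of the acinar, hormone and beta-cell lists passed the expression filter, so these lists were not tested. Of the sex genes, Ddx3y, on the Y chromosome, had 45 counts in HET 16, 11 in HOM 10, 7 in HET 10 and 1 in HOM 21, all male, and Xist had 17 counts in the female HET 11 alone. Tsix, the antisense gene of Xist on the X chromosome, had 9 counts in WT 12, 5 in HOM 10 and 1 each in WT 16 and HET 15, and does not tell the sexes apart where strand was not counted. The 6 libraries with neither Ddx3y nor Xist counts, the females WT 16 and HET 9 among them, also had 0 counts of Eif2s3y, Kdm5d and Uty, so their stated sex could not be checked.

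**Figure D2:**
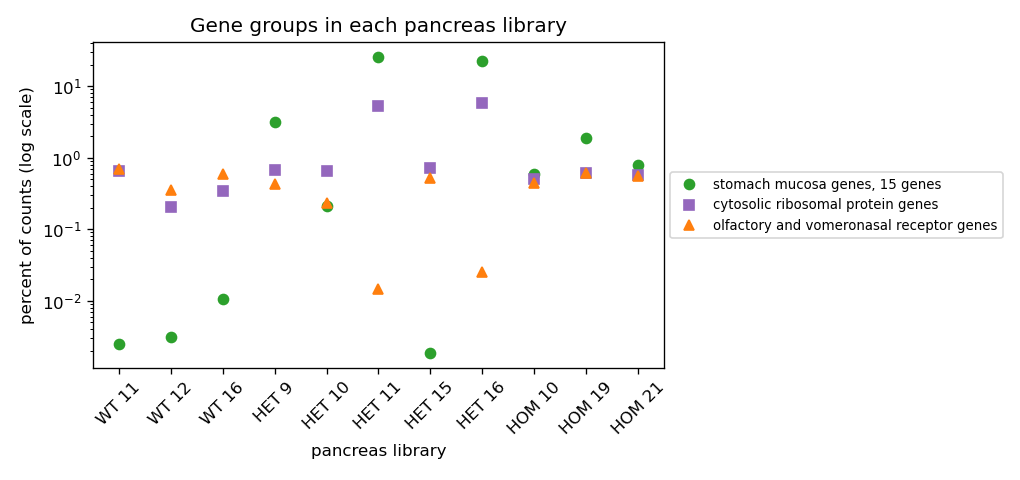
Percent of counts (vertical axis, log scale) taken by 3 gene groups in each of the 11 pancreas libraries (horizontal axis). In HET 11 and HET 16 the 15 stomach mucosa genes reach 25.4% and 22.3% and the olfactory and vomeronasal receptor genes stay at 0.0147% and 0.0252%, against 0.233% to 0.695% for the receptors in the other 9.

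Loss of both Otub2 copies was compared with none in 3 HOM and 3 WT pancreata. Genes of oxidative phosphorylation encoded in the nucleus, the subunits of the respiratory chain and ATP synthase, rose as a list in HOM. Of 24 tested members 22 were higher, and the list took 0.328% ± 0.0931 of counts in HOM and 0.0740% ± 0.0524 in WT (SD, n = 3 each; limma's camera, adjusted p = 6.33e-04, and adjusted p = 0.528 with an estimated correlation). Cox6b1 had 0 counts in WT, which allows up to 9.00 CPM over the group, and 111 ± 93.7 CPM in HOM. Ndufb9 had 1.77 ± 3.06 CPM in WT and 199 ± 44.2 in HOM, and Ndufa11 0 and 126 ± 148. Duct cell markers also rose as a list, with 6 of 7 higher (0.223% ± 0.0257 of counts against 0.176% ± 0.0356; camera adjusted p = 0.0166, and adjusted p = 0.528 with an estimated correlation). Krt19, a duct keratin, had 698 ± 366 CPM in HOM and 10.5 ± 18.2 in WT. Tff2, a trefoil peptide that is also among the stomach genes, had 193 ± 177 CPM in HOM and 0 counts in WT. Transcripts encoded in mitochondrial DNA fell as a list, with 7 of 7 lower (0.0917% ± 0.0505 against 0.360% ± 0.248; camera adjusted p = 0.00267, and adjusted p = 0.487 with an estimated correlation). Among them mt-Nd5, a subunit of complex I, had 212 ± 180 CPM in HOM and 1497 ± 1615 in WT, and the ribosomal RNA mt-Rnr1 39.5 ± 22.2 and 377 ± 208. Adjusted over the list alone, 0 members of these 3 lists passed. Without WT 11, which had 3362 CPM of mt-Nd5 and 0.640% of counts in the list, the WT means were 565 CPM and 0.220%. The stomach mucosa genes, by comparison, took 1.09% ± 0.704 of counts in HOM and 0.00541% ± 0.00452 in WT (SD, n = 3 each, not tested). Measures of library quality parted the same groups: Gm10800, a predicted gene, took 0.249% to 1.20% of counts in HOM and 1.29% to 4.91% in WT, and ribosomal RNA genes 0.143% to 0.197% and 0.101% to 0.137% (not tested). The other 6 lists tested, among them ribosomal proteins and interferon-stimulated genes, had adjusted p = 0.124 to 0.893.

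No single gene passed in HOM against WT. Of 3719 genes, edgeR called 0 at an adjusted p under 0.05 and 185 had an unadjusted p under 0.05, where chance gives 186. The lowest adjusted p was 0.957. The lowest p values in the higher direction belonged to Prkcsh, the beta subunit of glucosidase II (550 ± 261 CPM in HOM, 0 counts in WT), Slc25a39, a mitochondrial carrier (514 ± 390 against 1.77 ± 3.06 CPM), Clcn5 (227 ± 223 against 0), Ptk6 (213 ± 129 against 0) and Rpl37 (191 ± 330 against 0). In the lower direction these were Mrps18a (0 counts in HOM, 286 ± 437 CPM in WT), Rpl36a (0, 338 ± 345), Kdm2b (0, 146 ± 133), Mtx1 (0, 181 ± 313) and Fam50a (0, 194 ± 336). Mtx1 was counted in WT 11 alone of the WT and HOM libraries, Fam50a in WT 12 alone and Rpl37 in HOM 19 alone, and without that library both groups had 0 counts. Ribosomal protein genes have many processed copies, so reads of Rpl37 and Rpl36a could have been split by the counting. DESeq2 called 5 genes, which were named after their values were seen: Sympk higher in HOM, and Lsamp, Snrpd2, Flywch1 and Cntfr lower. The fitted log2 values were 21.4 for Sympk and −22.0, −20.1, −20.3 and −19.3 for the others. Folds of this size exceed the total counts of any WT or HOM pancreas library, so these are no measured folds. Without HET 11 and HET 16, left out after the data were seen, edgeR called 13 genes and 0 of the 5 lists that still had enough members for a test, and without HET 16 alone 4 genes. The duct list was not among those 5, nor among the 5 lists tested without HET 11 or without HET 16. The number of lists was 1 without WT 11, WT 16 or HOM 19: oxidative phosphorylation reached adjusted p = 0.854 without WT 16 and 0.232 without HOM 19, the mitochondrial list 0.293 without WT 11, and the duct list 0.0526 to 0.854 without WT 11, WT 16, HET 10, HET 15, HOM 19 or HOM 21. With no sex covariate the oxidative phosphorylation and duct lists were at 0.168 and 0.307, and with the size factors of DESeq2 the duct list was at 0.0972.

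HET pancreata differed from WT pancreata (5 against 3) in 5 of 9 tested lists, all higher in HET. Oxidative phosphorylation genes were higher in 23 of 24 members, at 1.77% ± 1.88 of counts in HET (SD, n = 5) and 0.0740% ± 0.0524 in WT (SD, n = 3; camera adjusted p = 2.05e-15, and adjusted p = 0.176 with an estimated correlation). Adjusted over the list alone, 16 members passed. Ndufv1, a complex I subunit, had 261 ± 226 CPM in HET and Atp5g1, of ATP synthase, 227 ± 208, and both had 0 counts in WT. Ribosomal protein genes were higher in 27 of 30 (2.63% ± 2.68 against 0.399% ± 0.225; camera adjusted p = 2.01e-12, and adjusted p = 0.176 with an estimated correlation), with 10 passing when adjusted over the list alone. Rps14 had 600 ± 789 CPM in HET and 0 counts in WT, and Rplp0 358 ± 417 and 1.77 ± 3.06 CPM. Duct cell markers were higher in 6 of 7 (0.699% ± 0.534 against 0.176% ± 0.0356; camera adjusted p = 4.85e-05, and adjusted p = 0.176 with an estimated correlation), 6 of them passing when adjusted over the list alone. Krt7, Krt8 and Muc1 had 203 ± 242, 364 ± 470 and 514 ± 539 CPM in HET and 0 counts in WT. The pancreatitis and regenerating genes, of which Krt7 and Krt19 are also duct markers, were higher in 5 of 5 (0.521% ± 0.360 against 0.0996% ± 0.0256; camera adjusted p = 0.0105, and adjusted p = 0.176 with an estimated correlation; 1 passing when adjusted over the list alone). Antioxidant and NRF2 target genes were higher in 6 of 9 (camera adjusted p = 0.0367, and adjusted p = 0.280 with an estimated correlation), with 3 passing when adjusted over the list alone. Among these were Sod1, which removes superoxide (229 ± 228 CPM, 0 counts in WT), and the metallothionein Mt1 (620 ± 728, 0 counts in WT). The share of stomach mucosa genes was 10.2% ± 12.6 in HET and 0.00541% ± 0.00452 in WT. HET 11 and HET 16 carried 25.4% and 22.3%. Scaled by total counts, 24 of the ribosomal and 4 of the pancreatitis genes were higher. Gm10800 took 0.0167% to 1.20% of counts in HET and 1.29% to 4.91% in WT, and ribosomal RNA genes 0.214% to 15.0% and 0.101% to 0.137%, so these measures of library quality parted the same groups (not tested).

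Single genes in HET against WT came close to the threshold without passing it. With edgeR 0 of 3719 genes had an adjusted p under 0.05, 517 had an unadjusted p under 0.05 (chance, 186), and the lowest adjusted p was 0.0518. A regrouping of these libraries that mixed the genotypes gave 806 such genes, so the excess over 186 need not come from genotype. DESeq2 called 149 genes, 116 higher and 33 lower. The lowest p values toward higher expression belonged to 5 genes with 0 counts in WT: the kinase gene Dapk3 (196 ± 272 CPM in HET), Camsap3 (192 ± 225), the proteasome subunit gene Psmd4 (203 ± 257), Snx17 (187 ± 273) and Pdap1 (247 ± 284). Toward lower expression they belonged to 5 genes with 0 counts in HET, which allows up to 1.31 CPM over the group: Ppara, a nuclear receptor of fatty acid oxidation (207 ± 209 CPM in WT), Rab42 (316 ± 181), Cdk17 (341 ± 323), Mss51 (267 ± 316) and Unc45bos (288 ± 252), an antisense gene whose reads cannot be told from those of its partner if strand was not counted. Without HET 11 and HET 16 edgeR called 9 genes and 0 of 5 lists, with adjusted p = 0.581 for oxidative phosphorylation and 0.773 for ribosomal proteins. It called 43 genes without HET 9, 92 without HET 15, 146 without the sex covariate and 23 when scaled by total counts. Lists called numbered 8 without WT 11, WT 12 or any of the 3 HOM libraries, 2 without WT 16, HET 11 or HET 16, and 3 without HET 15. Without HET 11, HET 16 or both, 5 lists could be tested, and the duct, pancreatitis and NRF2 lists had too few members left, as had the pancreatitis list without HET 15, so these calls could not be repeated there. The duct list had adjusted p = 0.331 without WT 16, the pancreatitis list 0.331 without WT 16 and 0.127 without HET 10, and the NRF2 list 0.110, 0.636 and 0.334 without WT 16, HET 9 and HET 15, and 0.0730 with the size factors of DESeq2.

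HOM pancreata had lower values than HET pancreata (3 against 5) in 5 of 9 lists. Ribosomal protein genes were lower in 28 of 30 members (0.563% ± 0.0535 of counts in HOM, SD, n = 3, and 2.63% ± 2.68 in HET, SD, n = 5; camera adjusted p = 9.50e-08, and adjusted p = 0.384 with an estimated correlation). Rpl36 had 236 ± 248 CPM in HET and 0 counts in HOM, and Rpl9 103 ± 94.4 and 0. Oxidative phosphorylation genes were lower in 24 of 24 (0.328% ± 0.0931 against 1.77% ± 1.88; camera adjusted p = 1.29e-05, and adjusted p = 0.423 with an estimated correlation). In both of these lists 4 members passed when adjusted over the list alone. Mitochondrial DNA transcripts were lower in 7 of 7 (camera adjusted p = 0.00133, and adjusted p = 0.280 with an estimated correlation), although their share of counts was 0.0917% ± 0.0505 and 0.111% ± 0.0509. mt-Rnr2 had 28.9 ± 32.1 CPM in HOM and 202 ± 134 in HET. Proteasome subunits were lower in 7 of 8 (0.146% ± 0.0442 against 0.293% ± 0.0570; camera adjusted p = 0.00354, and adjusted p = 0.123 with an estimated correlation), for example Psmd3 with 7.77 ± 13.5 and 71.7 ± 38.4 CPM. Antioxidant and NRF2 targets were lower in 6 of 9 (camera adjusted p = 0.0190, and adjusted p = 0.280 with an estimated correlation). Adjusted over the list alone, 0 mitochondrial, 1 proteasome and 1 NRF2 gene passed. The HET libraries rich in stomach genes, HET 11 and HET 16, held 5.30% and 5.81% of their counts in ribosomal protein genes and 3.76% and 3.85% in oxidative phosphorylation genes. Scaled by total counts, 23 of the ribosomal, 21 of the oxidative phosphorylation, 5 of the mitochondrial and 5 of the NRF2 genes were lower. Ribosomal RNA genes took 0.143% to 0.197% of counts in HOM and 0.214% to 15.0% in HET (not tested).

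Among single genes in HOM against HET, edgeR called 0 of 3719, with 410 at an unadjusted p under 0.05 (chance, 186) and a lowest adjusted p of 0.112. A mixed regrouping of these libraries gave 828 at an unadjusted p under 0.05, so this excess need not come from genotype either. DESeq2 called 27, all lower in HOM. Ppara was the best known of the genes leaning higher, with 471 ± 256 CPM in HOM and 0 counts in HET. The others were AA386476 (241 ± 185), Nwd2 (265 ± 188), Mkln1os (277 ± 280), an antisense gene, and Olfr51 (238 ± 259), an olfactory receptor gene of a large family whose members can share reads. The 5 leaning lower had 0 counts in HOM, which allows up to 7.80 CPM over the group: Rara, the retinoic acid receptor alpha (246 ± 351 CPM in HET), Gna11, a G protein subunit (312 ± 201), Zfpm1 (216 ± 235), Psmd4 (203 ± 257) and Dapk3 (196 ± 272). Without HET 11 and HET 16, edgeR called 7 genes and 0 of 5 lists, and the ribosomal and oxidative phosphorylation lists turned to the higher direction (adjusted p = 0.726 and 0.566). Without HET 16 alone 1 of 5 lists was called, the mitochondrial one: adjusted p was 0.0830 for ribosomal proteins, 0.464 for oxidative phosphorylation and 0.0632 for the proteasome, and the NRF2 list had too few members left for a test, as it had without HET 11 and without both. The NRF2 list was at 0.0660 to 0.658 without HET 9, HET 10, HET 15, HOM 10 or HOM 21.

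The fold changes of HOM and of HET against the same 3 WT libraries were correlated across 3719 genes, which are not independent replicates (Pearson r = 0.595). Counts of all pancreas libraries, WT included, simulated with no genotype effect gave r = 0.549 ± 0.0157 (SD over 50 draws, 0.505 to 0.578). Genes were drawn independently of each other, so this spread may be too narrow, and whether the observed r exceeds chance stays open. The covariance was 5.55, the simulated covariance 2.95 and the difference 2.59. Fold changes had the same sign in 72.4% of genes, against 67.9% simulated. Both comparisons called 0 genes with edgeR, so the overlap of calls was 0, with 0 from independent lists. The 3 WT libraries cannot be split into a pair of equal groups. The simulated HOM and HET groups also shared their WT libraries, so the simulated values already hold the part due to shared controls. This holds as far as the simulated spread matches the real one, and the source of the excess was not tested. The r was 0.460 without HOM 19 and 0.680 without HET 16.

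Female and male pancreata were compared as a check of the labels, with genotype in the model. Xist and the Y-linked genes had too few counts to enter the test. No gene passed: edgeR called 0 of 3719, with 147 at an unadjusted p under 0.05 (chance, 186), and 2 without HET 16. The lowest p values belonged to Gsr, glutathione reductase, with Wdr90, Xpo6, Otx2 and Clcn5 toward higher values in females, and Tie1, an endothelial receptor, with Synpr, Cep152, Ptchd4 and Dtl toward lower values (edgeR adjusted p = 1 for each). DESeq2 called Tle4, higher in females, named after its value was seen. Whether the HET effect differed between the sexes was tested in the 8 WT and HET pancreata. Only 1 WT female, WT 16, was among them, so the HET effect in females rests on that library. With edgeR 0 of 2400 genes passed and 59 had an unadjusted p under 0.05 (chance, 120). The lowest p values belonged to Edil3, Olfr1535, Mon2, Blnk and Tbcel (edgeR adjusted p = 1.00 for each). DESeq2 called Espn, Mtdh and Rpl32, named after their values were seen. Their fitted log2 values of −21.1, −20.1 and −20.7 are too large to be taken as measured folds.

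HET livers had higher values than WT livers (5 against 2) of genes that are more active in male than in female mouse liver. All 20 tested members of the male-biased list were higher in HET (19 when scaled by total counts), with a median log2 fold change of 1.18, and the list took 2.08% ± 0.424 of counts in HET (SD, n = 5) and 1.16% ± 0.141 in WT (SD, n = 2; camera adjusted p = 5.13e-08, and adjusted p = 0.203 with an estimated correlation). Hsd3b5, a steroid dehydrogenase, had a log2 fold change of 2.00 ± 0.50 (SE), the organic anion transporter gene Slco1a1 1.30 ± 0.34, the major urinary protein gene Mup21 1.43 ± 0.39 and the complement gene C8b 1.07 ± 0.34. Adjusted over the list alone 7 members passed, and over all genes 0 did (edgeR adjusted p = 0.219 to 0.281 for these 4). The list was called in each fit that left out 1 library. The sex of the livers was not stated. Xist had 0 counts in all 7, and the Y-linked genes had 2 and 4 counts in WT and 2 to 11 in HET, which scaled to library size was 12.3 ± 0.857 CPM in WT (SD, n = 2) and 9.24 ± 5.26 in HET (SD, n = 5). Female-biased genes, too few for a test, took 0.0169% ± 0.00835 of counts in WT and 0.00679% ± 0.00395 in HET.

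**Figure D3:**
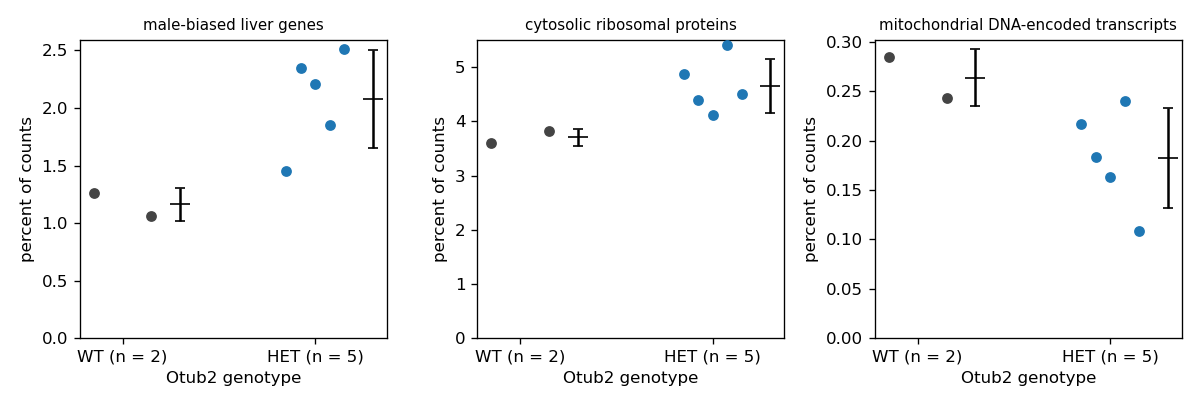
Percent of counts (vertical axis) taken by male-biased genes, cytosolic ribosomal protein genes and mitochondrial DNA transcripts in each liver by genotype (horizontal axis); points are libraries and bars the mean ± SD. Male-biased genes take 1.16% ± 0.141 in 2 WT and 2.08% ± 0.424 in 5 HET livers.

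Another 8 of 28 lists passed in liver, 7 upward and 1 downward. Other measures also parted the genotypes: olfactory and vomeronasal receptor genes took 0.00966% and 0.0111% of counts in WT and 0.000652% to 0.00651% in HET, and Gm10800 0.137% and 0.194% in WT and 0% to 0.115% in HET (not tested). Ribosomal protein genes were higher in 68 of 74 members (median log2 fold change 0.54; 4.66% ± 0.500 of counts in HET, SD, n = 5, and 3.71% ± 0.160 in WT, SD, n = 2; camera adjusted p = 2.42e-13, and adjusted p = 0.185 with an estimated correlation). Rpl22 had the lowest p among them, at 1.23 ± 0.32 (SE), and did not pass alone. Oxidative phosphorylation genes were higher in 59 of 72 (median 0.41; 3.49% ± 0.231 against 3.04% ± 0.107; camera adjusted p = 9.69e-09, and adjusted p = 0.203 with an estimated correlation), for example Ndufb2 at 1.22 ± 0.33 and Cox6c at 1.00 ± 0.29. Mitochondrial DNA transcripts went the other way, lower in 8 of 8 (median −0.78; 0.182% ± 0.0510 against 0.264% ± 0.0288; camera adjusted p = 6.50e-04, and adjusted p = 0.478 with an estimated correlation). mt-Nd1 stood at −1.38 ± 0.40 and mt-Nd2 at −1.17 ± 0.38, the 2 members that passed when adjusted over the list alone. Proteasome subunits were higher in 22 of 29 (median 0.36; camera adjusted p = 0.00140, and adjusted p = 0.478 with an estimated correlation), with Psmc2 at 1.22 ± 0.47. Pericentral hepatocyte genes, active around the central vein, were higher in 11 of 14 (median 0.53; camera adjusted p = 0.00284, and adjusted p = 0.546 with an estimated correlation). Their share of counts was 0.833% in WT 1, 0.502% in WT 2, 0.775% to 0.930% in HET 1 to HET 4 and 1.38% in HET 5, so WT 1 lay within the HET range. Cyp2e1, an ethanol-oxidising P450, stood at 0.71 ± 0.30, and Cyp2a5 at 1.29 ± 0.36, which shares sequence with Cyp2a4 so that reads can be split between them. Acute-phase genes were higher in 25 of 27 (median 0.54; camera adjusted p = 0.0349, and adjusted p = 0.735 with an estimated correlation), genes of the unfolded protein response in 15 of 21 (median 0.36; 0.0290, and adjusted p = 0.620 with an estimated correlation) and hepatocyte secreted proteins in 25 of 32 (median 0.19; 0.0260, and adjusted p = 0.478 with an estimated correlation). The summed share of the secreted proteins went the other way, 23.7% ± 0.357 in HET and 25.2% ± 1.52 in WT. Xbp1, a transcription factor of the unfolded protein response, stood at 0.88 ± 0.32 and Orm1, an acute-phase glycoprotein, at 1.43 ± 0.63. Adjusted over the list alone, 1 pericentral gene passed and 0 genes of the ribosomal, respiratory, proteasome, acute-phase, unfolded protein and secreted lists. Calls fell to 5 lists without WT 2, where the unfolded protein list turned lower (adjusted p = 0.928) and the proteasome, secreted and pericentral lists reached 0.194, 0.186 and 0.669. The mitochondrial list was at 0.0504 without WT 1, the acute-phase list at 0.0961 to 0.370 without WT 1, HET 2 or HET 3, the unfolded protein list at 0.0630 and 0.172 and the secreted list at 0.0630 and 0.0662 without HET 2 and HET 5, and the secreted list at 0.0881, with 18 of 32 higher, when scaled by total counts.

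Single liver genes did not pass with edgeR: 0 of 4803 had an adjusted p under 0.05 and 497 an unadjusted p under 0.05 (chance, 240). The lowest adjusted p was 0.0681. A regrouping of the livers that mixed the genotypes gave 583 genes with an unadjusted p under 0.05, so the excess over 240 need not come from genotype. Wfdc21, an acute-phase gene, had 1090 ± 100.5 CPM in HET and 291 ± 144 in WT, a log2 fold change of 2.01 ± 0.35 (SE, adjusted p = 0.0681). Mup5 had 434 ± 177 and 62.0 ± 21.7 CPM (2.97 ± 0.55, adjusted p = 0.0960). Rarres1, Hint1 and the serpin gene Serpina3k stood at 2.48 ± 0.59, 1.45 ± 0.35 and 1.28 ± 0.31 (adjusted p = 0.186 for each). In the lower direction Malat1, a nuclear noncoding RNA, stood at −2.33 ± 0.39 (186 ± 50.7 CPM in HET, 1001 ± 896 in WT) and the female-biased P450 gene Cyp2a4 at −3.41 ± 0.63 (7.90 ± 4.72 and 81.5 ± 78.8 CPM), both with adjusted p = 0.0681. Pabpn1, Col5a3 and Hamp2, a hepcidin gene, stood at −2.57 ± 0.54, −2.10 ± 0.47 and −2.53 ± 0.51 (adjusted p = 0.144, 0.161 and 0.179). The Mup, Serpina3, Cyp2a and hepcidin genes belong to families with near-identical copies, so their separate counts are uncertain. DESeq2 called 10 genes, 8 higher and 2 lower: Wfdc21, Mup5, Serpina3k, Hint1 and Hsd3b5 higher, Malat1 and Hamp2 lower, and Mup15, Mup18 and Mup11 higher, these last named after their values were seen. The edgeR count was 57 with no expression filter, 6 at a mean of at least 10 CPM, 4 without WT 1, 1 without HET 1 and 6 without HET 5.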

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

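The tests below were chosen after the results they bear on were seen, except the thinning of the livers to equal depth for the male-biased list, which was set before. Of 45 groups of library values examined, 5 held a library far from the others. The bound used is passed by about 1 in 20 groups of independent, normally distributed values. These groups shared libraries and some held many 0 values, so the 5 cannot be set against that rate. In HET pancreas, HET 9 had 15.0% of its counts in ribosomal RNA genes (Wilson interval 14.7 to 15.4), with 0.214% to 3.58% in the other 4. HET 15 had 0.200% in mitochondrial DNA transcripts (0.180 to 0.223), with 0.0777% to 0.0995% in the others. HET 16 had 1.49 CPM of Otub2, a single count, with 0 in the others, a pattern that always passes the bound. In HET liver, HET 5 had 1.38% in pericentral genes (1.36 to 1.39), with 0.775% to 0.930% in the others, and HET 1 had 229 CPM of Hamp2, with 44.4 to 91.3 in the others.

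Acinar enzymes took 16.5% of counts in HET 11 and 6.31% in HET 16. Of their 219011 counts in HET 11, Clps held 188192 and Pla2g1b 30561, and of their 42301 in HET 16 Clps held 25493. In the same libraries stomach mucosa genes took 25.4% and 22.3% of counts. Stomach tissue taken with the pancreas may be the source: with every pancreas library thinned to 49502 counts, 7 to 11 of 20 further stomach genes that had not been looked at were detected in HET 11 and 4 to 9 in HET 16 over 20 draws, and 1 to 4 in the others, yet at full depth their counts over those of intestine genes came to 3.67 and 2.99, no higher than the 3.87 of another pancreas library, so the test does not decide. The bound first set for this ratio was 1, which 2.99 passes, and it was changed after the ratios of the other libraries were seen. Loss of acinar enzyme reads in the counting also stays open, since 11 of 30 acinar enzymes reached 10 counts in some library (9 in a pancreas, 4 in a liver) and 11 had 0 everywhere. Outside this list Eef1a1 had 0 counts in HET 11 and HET 16, but Actb had 18295 and 8636, which does not decide it for the enzymes. Both libraries are HET, so genotype is not excluded, but the other 3 HET pancreata held 0.00184% to 3.11%, and no biological explanation was tested.

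The other 9 pancreas libraries, of all 3 genotypes, had 0.233% to 0.695% of counts in olfactory and vomeronasal receptor genes, which these tissues hardly express, against at most 0.0252% in HET 11, HET 16 and the livers. In 8 of them the 10 leading genes took 2.44% to 8.68% of counts, against 18.1% to 45.5% in HET 11, HET 16 and the livers. HET 9 was not flat in this way, at 22.0%, with 7363 of its 49502 counts in the ribosomal RNA gene CT010467.1. Low depth alone is argued against: 3 of the 9 libraries were deeper than the shallowest liver and still held at least 0.438%, where that liver held 0.00966%. Reads from genomic DNA or unspliced RNA remain a candidate explanation, since counts rose with the span of the gene in each of the 9 libraries (rank correlation at least 0.112, at most 0.178) and fell with it in the other 9 (−0.236 to −0.129). This test took the place of an earlier one on the receptor share, which defines the pattern. What the submitters' correction did to these counts is not known, and no biological explanation was tested. Shares of Gm10800 and ribosomal RNA genes parted WT from HET and from HOM pancreata, and the ribosomal RNA share also HOM from HET, with no overlap, so an effect of library quality on the lists called in these 3 comparisons stays open and untested.

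Male-biased genes and 8 other lists were called in HET liver, where the WT livers also held more receptor genes (0.00966% and 0.0111% of counts, HET 0.000652% to 0.00651%). Depth as the whole cause is argued against for 4 lists: with each liver thinned to 155201 counts, the male-biased, ribosomal, oxidative phosphorylation and mitochondrial lists were called in the same direction in 20 of 20 draws, with medians of 0.63 to 1.04, 0.37 to 0.49, 0.28 to 0.36 and −0.79 to −0.41. At full depth these medians were 1.18, 0.54, 0.41 and −0.78. The male-biased, ribosomal and oxidative phosphorylation medians were smaller in every draw, so depth as part of the cause stays open. For the other 5 lists a difference in depth stays open: pericentral genes were called in 10 of 20 draws and the rest in 0, all keeping their direction. Medians were 0.34 to 0.57 for pericentral (0.53 at full depth) and 0.30 to 0.50 for acute-phase genes (0.54), and fell to 0.13 to 0.30 for the proteasome (0.36), 0.01 to 0.27 for unfolded protein (0.36) and 0.02 to 0.11 for secreted protein genes (0.19). Since thinning also lowers the power of the test, the lost calls decide nothing. A female among the WT livers cannot be told apart from the effect of genotype by the sex genes, since the lower Y-linked count was 2 with 0 Xist counts. Scaled to library size, Y-linked genes were no lower in the WT livers (12.9 and 11.7 CPM) than in the HET livers (6.52 to 18.6), from few counts. The rank correlation of counts with gene span, unlike the receptor share, did not part the livers. It was −0.227 and −0.200 in WT, within the −0.236 to −0.158 of HET. Genotype, hormonal state, a larger share of genomic or unspliced reads in the WT livers and other differences between the animals stay open and untested, with 2 WT livers.

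Splits of the libraries into groups of the same sizes, the real one counted among them, gave as many lists in a share too large to exclude chance: 7 of 21 in liver (real 9, highest other 12), 12 of 55 in pancreas HET against WT (real 5, highest other 6) and 16 of 56 in HOM against HET (real 5, highest other 7). HOM against WT has 10 splits, too few for a share under 0.05, of which 4 gave as many lists (real 3, highest other 6). The same count for genes decides nothing, because the real grouping gave 0 genes and every split gives at least as many: 21 of 21 in liver (highest other 5), 55 of 55 in HET against WT (313), 56 of 56 in HOM against HET (295), 10 of 10 in HOM against WT (0) and 100 of 100 in female against male (210). Genes with an unadjusted p under 0.05 were also more numerous in some other split of each genotype comparison. They numbered 497 in liver (highest other 583), 517 in HET against WT (806), 410 in HOM against HET (828) and 185 in HOM against WT (313). The splits with most genes in HET against WT and in HOM against HET set HET 11 and HET 16 together against other libraries. This grouping differs from the genotype labels, but both libraries are HET, and its cause was not tested.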

How the results depend on the processing

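Total-count scaling, the fits without HET 11 and HET 16, the Otub2 permutation tests and the fits of lists, Otub2, sex, interaction and correlation that leave out 1 library were chosen after seeing the data. Where no cause is given, the cause was not tested. Genes called (edgeR, 0 in each comparison as reported): HOM against WT 5 with DESeq2, 5 with only the 2 groups, 13 without both libraries and 0 to 4 leaving out 1 library (4 without HET 16). HET against WT 149 with DESeq2, 146 without the sex covariate, 23 with total counts, 9 without both, 0 to 92 leaving out 1 library (43 without HET 9, 92 without HET 15). HOM against HET 27 with DESeq2 and 7 without both. Liver 10 with DESeq2, 57 with no filter, 6 at a mean of 10 CPM, 0 to 6 leaving out 1 library (4 without WT 1, 1 without HET 1, 6 without HET 5). Female against male 1 with DESeq2, 0 to 2 leaving out 1 library (2 without HET 16); interaction 3 with DESeq2. Lists called: 3, 5, 5 and 9 as reported (HOM against WT, HET against WT, HOM against HET, liver), 0 in each with an estimated correlation or fry, 0 in the 3 pancreas comparisons without both libraries, where 5 of the 9 lists could be tested. HOM against WT gave 1 without the sex covariate and 5 with total counts. Leaving out 1 library gave 1 to 4, 2 to 8, 1 to 6 and 5 to 10. Turned in direction: ribosomal and oxidative phosphorylation lists in HOM against HET without both libraries (adjusted p = 0.726 and 0.566), the unfolded protein list in liver without WT 2 (0.928; 0.00125 to 0.928 leaving out 1 library) and the fitted value of Otub2 in liver without WT 1 (log2 3.18; −1.72 to 3.18), where the WT left had 0 counts, so that 3.18 is no measured fold. In HOM against WT, Mtx1 without WT 11, Fam50a without WT 12 and Rpl37 without HOM 19 had 0 counts in both groups and gave no value. Otub2 with HET and HOM pooled lay −37.8 CPM from WT and passed, at the smallest p that its 165 splits allow. The correlation of HOM and HET effects was 0.497 at a mean of 10 CPM and 0.460 to 0.680 leaving out 1 library. Replicate block: same-numbered libraries did not deviate together (pancreas correlations 0.00597, −0.0484 and 0.0786, liver −0.0251 and −0.0274), in 3 and 2 pairs, so the numbers were not taken to pair the samples, and what they mark is not known. With the block, which leaves 1 residual degree of freedom in each tissue, 149 genes were called in pancreas HET against WT, 0 in HOM against HET and 41 in liver. Of the other results, single genes kept direction and side of the threshold in 824 alternatives and passed it in 61; single lists kept their call in 201 and lost it in 87; counts of calls stayed within 1.5 times in 114 and moved in 50. Rara under the replicate block, the interaction without WT 16 and Xist as a covariate in liver (0 counts in all) could not be fitted.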

Other observations

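The genes and shares below were picked after the data were seen, and tests were made only where an adjusted p is given. In liver the acute-phase genes Saa1 and Saa2 were uneven among HET animals: Saa1 had 4326 CPM in HET 2 and 8821 in HET 3 and 77.1 to 544 in the other 3 HET livers, with 567 and 703 in WT. Saa2 had 1942 and 9391 CPM in HET 2 and HET 3, 24.3 to 325 in the other 3 HET livers, and 322 and 534 in WT. B-cell and plasma-cell markers took 0.00872% ± 0.00407 of counts in WT liver (SD, n = 2) and 0.00206% ± 0.000258 in HET (SD, n = 5). Macrophage markers took 0.111% ± 0.0115 and 0.0813% ± 0.00996, with 9 of 12 lower in HET (camera adjusted p = 0.195). Bile acid genes were higher in 11 of 17 (adjusted p = 0.0714) and fatty acid oxidation genes in 21 of 31 (adjusted p = 0.0912), neither passing. HET 5, the deepest liver, held 94 counts of Ctrb1, a pancreatic chymotrypsinogen, and 650 of Dmbt1, a mucosal glycoprotein, where the other 6 livers held 0 of Ctrb1 and 0 to 8 of Dmbt1.

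In pancreas, Gm10800, a predicted gene that led several libraries, took 3.58% ± 1.99 of counts in WT (SD, n = 3), 0.500% ± 0.500 in HET (SD, n = 5) and 0.666% ± 0.485 in HOM (SD, n = 3). T-cell and NK-cell markers took 0.122% ± 0.0236 in WT, 0.0653% ± 0.0813 in HET and 0.152% ± 0.0556 in HOM. Keratin genes of skin and forestomach, a list drawn up after the stomach genes were seen, had 2935 CPM in HET 11 and 6696 in HET 16 and 0 to 1818 in the other 9. Intestine genes had 338 and 203 CPM in HET 11 and HET 16 and 0 to 990 in the other 9.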
